A study of Gallus gallus with 24 samples.

How the data were processed

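RNA abundance was measured in liver, whole brain, duodenum and breast muscle of Ross broilers, a commercial strain bred for rapid meat growth, at hatch (day 0) and at 7 days of age. The labels give every chick as male. For each tissue and age, 3 pools of total RNA were made, each from 4 to 5 chicks, and each pool was hybridised to its own array, which gave 24 arrays in 8 groups. Tissues were frozen in liquid nitrogen and RNA was extracted with Trizol, and biotin-labelled target was prepared from 2 µg of RNA, per the labels' protocols. The arrays carry short probes for chicken transcripts, grouped into probe sets that each give 1 signal. A probe set may match more than 1 transcript, and some were annotated to several genes.

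The deposited values are intensity on a linear scale, 1 signal per probe set and array, made with MAS5 per the submitters' processing notes. MAS5 combines probes that match a transcript with paired probes that carry a mismatch. Its version and settings are not given in the sources used here. After trimming 2% of the probe sets at each end, the mean signal was 500.1 or 500.2 on each array, so the arrays had been scaled to a common level before deposit. Scanner images, probe-level files and detection calls were not used here. Each probe set's signal is relative to the rest of its array, so a change of many abundant transcripts can shift the others. Signals of different genes were not set against each other.

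The table held 38535 probe sets, of which 96 control probe sets were left out of the tests. Signals were taken as log2(signal + 28.36), where 28.36 is the 25th percentile of all signals, and were not normalized further. Fold changes are on this scale, which understates the change of dim probe sets. Where a group mean lies near or below 28.36, the size of a change, and so its rank among the largest, depends on the value added. Probe sets were kept where the mean of at least 1 of the 8 groups reached 104.6, the median of all signals, which left 25758. A linear model with 8 group means was fitted to all 24 arrays with limma 3.58.1 in R 4.3.3, with empirical Bayes variances that follow the signal level (16 residual degrees of freedom, 7.94 from the prior). Age effects are day 7 minus day 0 within a tissue. Differences between age effects were tested with an F test over the 4 tissues and for each pair of tissues. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 and counted as enriched in a tissue where it was called and at least 4-fold above each of the other tissues. Each ± after a log2 change is its standard error from this fit, each ± after a signal is the SD over the pools, and n is 3 pools per group unless stated.

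Probe sets were named from the array's annotation table, which gave 27178 of them 1 gene symbol, 177 several and 11180 none. Symbols were brought up to date by gene number through the RefSeq gene table of the assembly GRCg7b, where 26863 of the 27178 matched. No genome build is named in the sources used here, so no coordinates are given. Where several probe sets name a gene, the one with the highest mean signal was used, which left 11444 genes, and probe sets that differ in their call are mentioned.

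Before the data were examined, 39 lists of genes were written from textbook knowledge of the 4 tissues, their metabolism and the cell types they may hold, together with the tests, the alternatives and the rule for the genes to be named. That rule took, per tissue, the 5 rising and 5 falling genes with the largest change among those called with no overlap between the pools of day 0 and day 7, and up to 3 called members of each list written for that tissue. It also took the 5 genes most enriched in each tissue, 6 genes called in opposite directions in 2 tissues with the largest difference, and up to 5 genes per direction called in all 4 tissues. Members named from other lists, up to 3 called ones per list and tissue by size of change, were chosen after their values were seen, as were 2 genes followed across the tissues in the closing section. Lists with at least 5 measured members were tested with camera, a limma test that sets a list against the other genes, with a preset correlation between genes of 0.01 and adjustment over lists and tissues together. The test was repeated with a correlation estimated for each list. A list is described as higher or lower where both versions passed 0.05, and the adjusted p with the estimated correlation is given wherever that call was lost. Where a list held, the adjusted p printed first is that with the preset correlation. The estimated correlation gave larger values, up to 0.0414 for fatty acid oxidation in liver. When the same arrays were split into other groups, the preset version still passed up to 13 lists in liver and 16 in duodenum. Its p-values therefore overstate the evidence.

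The age effects, the F test between tissues, the list test with the preset correlation and the tissue enrichment were tested on simulated data. These data had the arrays' own signal levels and 200 probe sets per fold size made to change. Of the probe sets changed 2-fold and kept, 42.1% were recovered in liver, 49.2% in whole brain, 47.2% in duodenum and 46.4% in breast muscle. For 4-fold changes the shares were 83.8%, 84.9%, 86.5% and 85.9%. The F test between tissues recovered fewer, 27.4% to 34% of the 2-fold and 69.8% to 73.6% of the 4-fold changes. Between 18 and 20 of 25539 to 25595 unchanged probe sets were called per tissue, and 0 changed probe sets were called in the wrong direction. The simulated noise had 1 spread per probe set, the same on each array. On the real arrays the root mean square deviation from the group means ran from 0.27 (breast muscle day 0 pool 3) to 0.547 (duodenum day 7 pool 1). The simulation therefore cannot give the rate of false calls under such uneven spread. With the preset correlation the shifted gene list was recovered and 0 of 151 unshifted lists were called, in simulated noise that was independent between genes. The list test with an estimated correlation, the pairs of tissues, the list differences and the count shared by the tissues were not simulated. Enriched probe sets were recovered at 92.1% in liver, 94.1% in whole brain, 92.1% in duodenum and 94.5% in breast muscle. In the same order, 35, 95, 37 and 34 were called that truly lay below the 4-fold threshold. Of these, 0, 1, 0 and 0 truly lay less than 2-fold above the next tissue.

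The alternatives written at the same time were 2 other values added before taking logs (the 10th percentile and the median), no filter and a stricter one at the 70th percentile, quantile normalization, centring of each array on its median, variances without a signal trend or with a robust prior, array weights, each tissue fitted alone, the replicate number as a block, a threshold of at least 2-fold, other set tests and leaving out each array in turn. Others were added after the data were examined: leaving out 2 duodenum or 2 brain arrays that stood apart, and the ratio of 5′ to 3′ signal as a covariate. The number of arrays limits the precision. Each pool was hybridised to its own array, so p-values rest on a spread that mixes differences between pools with labelling and array noise. In the main fit this spread was estimated for each probe set over all tissues together and moderated by the prior. A standard error or p-value given for a tissue therefore does not reflect the spread of that tissue's pools alone. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.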

Results

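Transcript signals were compared between hatch and day 7 in liver, whole brain, duodenum and breast muscle of broiler chicks, with 3 pools of RNA per tissue and age. The first week after hatch is the period in which chicks change from yolk to feed. No pair of arrays held identical values. Arrays of the same group correlated at 0.916 to 0.981 across probe sets, arrays of the same tissue but different age at 0.865 or more, and arrays of different tissues at no more than 0.804. Tissue separated the arrays on the first 3 principal components, which held 40.7%, 25.1% and 16.6% of the variance.

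**Figure D1:**
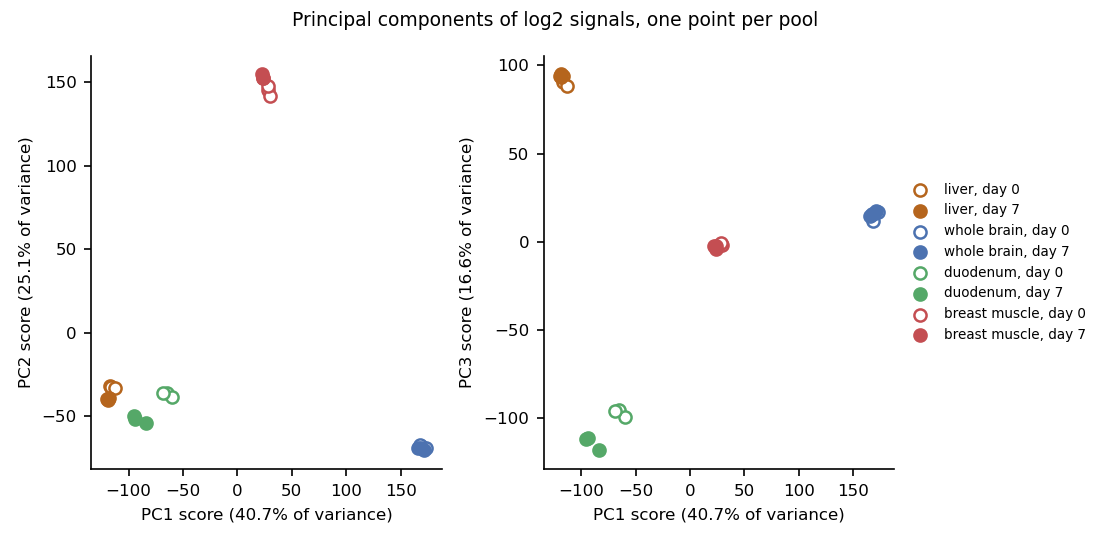
Scores of the 24 arrays on the first 3 principal components of log2 signals, with the share of variance on each axis, coloured by tissue, with day 0 open and day 7 filled. Each tissue forms its own cluster, and in duodenum the PC1 scores lie from -68.5 to -59.9 at day 0 and from -95.4 to -84 at day 7.

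Some arrays differed in ways the groups do not explain. The control transcripts added before hybridisation had a mean signal of 11500 on duodenum day 0 pool 2 and 19990 on duodenum day 7 pool 1, against 2490 to 6139 on the other 22 arrays. In brain, day 0 pool 1 and day 7 pool 3 had the lowest log2 ratios of 5′ to 3′ signal of control genes, -2.01 and -1.48, against -1.33 to -0.91 on the other brain arrays. HINTW, a gene of the female-specific W chromosome, had signals from 1797 to 15930 in these pools labelled male. Of 14 listed W-linked genes 2 were measured, and 0 of them were called for age in any tissue. With so wide a spread between pools, this does not show that W-linked signal was equal at the ages.

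Genes typical of each tissue were brightest there, as means over both ages. In liver 480 probe sets were enriched, led by the plasma proteins PIT54, ORM1, SPP2 and FGA and by A2ML4. PIT54, the haptoglobin-like carrier of birds, had a mean signal of 67100 ± 10600 in liver (n = 6 pools over both ages) and at most 12.8 in the other tissues. In brain 1643 were enriched, led by the transcription factor ZIC1, the glutamate receptor subunit GRIN1, the neurofilament NEFM, the glutamate transporter SLC1A3 and the synaptic protein SNAP25, which reached 31500 ± 2370 in brain against 180 ± 139 in duodenum. In duodenum 520 were enriched, led by the retinol carrier RBP2, the peptide transporter SLC15A1, the crypt gene OLFM4, the alkaline phosphatase ALPPL and CLCA1 of mucus cells. In breast muscle 599 were enriched, led by the fast troponin TNNI2, titin (TTN), the myosin light chains MYLPF and MYL1 and the creatine kinase CKMT2. The smallest log2 difference from another tissue among these 20 genes was 7.58, with adjusted p of 1.42e-16 or less. With other values added before taking logs these differences ran from 6.25 for GRIN1 to 11.87 for PIT54, so their size and order depend on that value.

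Between day 0 and day 7, 2958 of 25758 probe sets changed in liver (11.5%), 60 in whole brain (0.233%), 5948 in duodenum (23.1%) and 7058 in breast muscle (27.4%). Of these, 1370, 39, 2767 and 3597 changed at least 2-fold. Probe sets whose 3 pools of one age all lay above the 3 of the other made up 34.4%, 13.1%, 31.9% and 46.6% of those tested, where chance gives 10%.

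**Figure D2:**
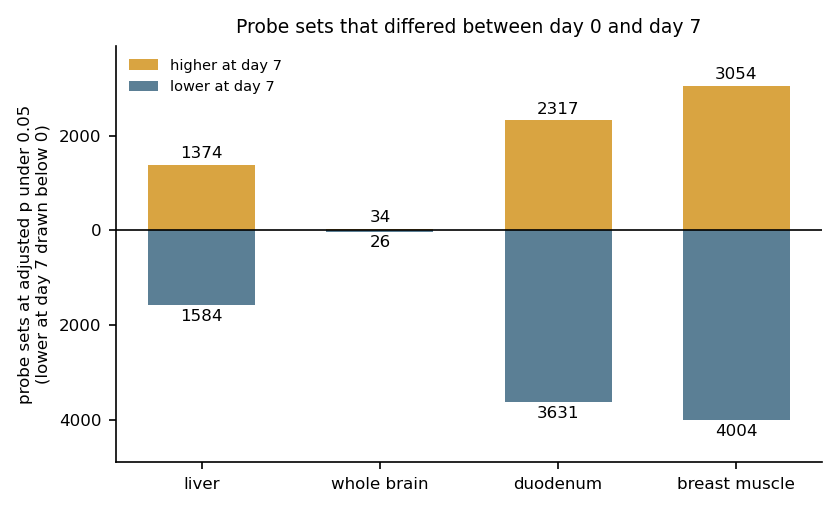
Number of probe sets at an adjusted p under 0.05 in each tissue, with those higher at day 7 above 0 and those lower at day 7 below 0. Breast muscle has the most, 3054 and 4004, and whole brain the fewest, 34 and 26.

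In liver, genes of fat and cholesterol synthesis rose by day 7. Of 19 measured lipogenesis genes, 14 rose and 0 fell, with a median log2 change of 2.03, and the count was also 14 adjusted over the list alone. The camera adjusted p was 3.61e-23, and 2.36e-06 with an estimated correlation. THRSP, a nuclear protein that promotes lipogenic transcription, rose from a signal of 212 ± 34.8 to 60300 ± 4750, a log2 change of 7.98 ± 0.40 (adjusted p = 3.64e-13). The fatty acid desaturases FADS2, SCD and FADS1 rose to signals of 11900 ± 3250, 4040 ± 738 and 5200 ± 635, with log2 changes of 7.33 ± 0.33 for FADS2 (6.25 to 8.04 with other added values) and 6.51 ± 0.37 for SCD (5.08 to 7.55). Of 17 measured cholesterol synthesis genes, 16 rose and 0 fell, by a median of 2.84 (16 adjusted over the list alone). For this list the camera adjusted p was 8.52e-37, and 2.15e-06 with an estimated correlation. SQLE, an oxygenase of the pathway, rose from 102 ± 26.8 to 8680 ± 1630, by 6.06 ± 0.20, the sterol cyclase LSS by 4.64 ± 0.17 and NSDHL by 4.31 ± 0.17.

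Fatty acid oxidation and ketogenesis moved the other way in liver. Of 22 measured genes, 9 fell and 1 rose (median -0.32, adjusted p = 0.000164, and 0.0414 with an estimated correlation). Adjusted over the list alone, 10 fell and 1 rose. PDK4, which restrains glucose oxidation, fell from 11900 ± 803 to 2670 ± 96.8 (log2 change -2.15 ± 0.22). The coactivator PPARGC1A changed by -1.89 ± 0.17 and the carnitine transferase CPT1A by -1.89 ± 0.41. Cell cycle genes fell too, 39 of 59 against 1 that rose (median -0.90, adjusted p = 1.23e-18, and 0.00833 with an estimated correlation). Adjusted over the list alone, 48 fell. The replication genes MCM3, MCM2 and GINS1 changed by -1.78 ± 0.38, -1.60 ± 0.21 and -1.58 ± 0.24.

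Genes of antigen presentation, T cells and interferon response rose in liver, while myeloid and innate defence genes moved both ways, with 12 of 27 higher and 6 lower (adjusted p = 0.0566). Antigen presentation genes rose in 9 of 11 cases (median 1.54, adjusted p = 2.66e-13, 9 adjusted over the list alone), led by the class II genes BLB1 at 3.02 ± 0.18 and CD74 at 2.70 ± 0.16 and the class I gene BF2 at 1.98 ± 0.23. Of 13 T cell and cytotoxic cell genes 7 rose and 0 fell (median 1.11, adjusted p = 8.79e-07, 9 adjusted over the list alone), with CD3E and CD3D of the T cell receptor complex at 3.10 ± 0.37 and 2.46 ± 0.33 and the cytotoxic protein GNLY at 2.07 ± 0.21. Of 22 interferon response genes 7 rose and 0 fell (median 1.07, adjusted p = 4.11e-08), and 15 rose adjusted over the list alone. IFI27L2 rose by 4.18 ± 0.24, DDX60 by 1.96 ± 0.46, with 1 of its 2 other probe sets called, and IRF1 by 1.45 ± 0.22. Haemoglobin and other red blood cell genes, markers of blood in the sample, rose in 4 of 15 cases and fell in 1 in liver (median 0.22, adjusted p = 0.0403, and 0.196 with an estimated correlation).

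Among genes whose pools did not overlap between ages, the largest falls in liver were of DIO3, which inactivates thyroid hormone, from 3620 ± 2440 to 252 ± 294 (log2 change -3.83 ± 0.62), CHAC1, a glutathione-degrading stress gene (-3.76 ± 0.29), LHFPL5 (-3.63 ± 0.24), LECT2 (-3.24 ± 0.43) and REG1A (-3.22 ± 0.34, and -4.38 to -1.93 with other added values, which its rank depends on). LECT2, listed here with myeloid and innate defence genes, also changed by -3.31 in breast muscle. Other lists written for liver did not pass camera. Of 27 plasma protein genes 1 rose, HPX by 1.22 ± 0.27 (list adjusted p = 0.0992, also 1 adjusted over the list alone). Of 13 gluconeogenesis genes 3 fell and 1 rose (adjusted p = 0.0916, and 6 fell and 1 rose adjusted over the list alone), with PCK1, a rate-limiting enzyme, at -1.13 ± 0.35, GOT1 at -0.54 ± 0.11 and LDHA at 0.89 ± 0.21. Of 22 xenobiotic and bile acid genes 3 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.308), among them the glutathione transferase GSTA2 at 2.84 ± 0.19, CYP7A1, the rate-limiting enzyme of bile acid synthesis, at 1.34 ± 0.35 and CYP1A1 at -2.26 ± 0.35. Of 23 amino acid catabolism genes 2 rose, ACMSD by 1.52 ± 0.32 and HGD by 0.99 ± 0.32, and 1 fell, BCKDHB, at -0.86 ± 0.17 (adjusted p = 0.813, 2 and 2 adjusted over the list alone). Plasma proteins passed with liver fitted alone (adjusted p = 5.04e-05) and with the median signal added before taking logs (0.0152). Gluconeogenesis passed with quantile normalization (0.0224). The limma test fry sets a list against no change and not against the other genes, so it answers another question than camera. With fry, gluconeogenesis (0.000532) and xenobiotic genes (0.03) passed.

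In all, 1374 probe sets rose and 1584 fell in liver, and the share of higher calls, 46.5%, became 38.7% with median centring. Of 38 lists 11 passed camera. Of these 11, 7 held with an estimated correlation. Those lost besides red blood cells were B cells (2 of 12 rose, adjusted p = 0.0255, and 0.196 with an estimated correlation), extracellular matrix (8 of 35 fell, 0.0054, and 0.161 with an estimated correlation) and oxidative phosphorylation (19 of 62 fell, 1.45e-05, and 0.325 with an estimated correlation). Array weights raised the count to 4924, and the calls of HGD (11 of 18), PCK1 (5 of 18), CYP7A1 (3 of 18) and LDHA (1 of 18) were lost under some alternatives.

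**Figure D3:**
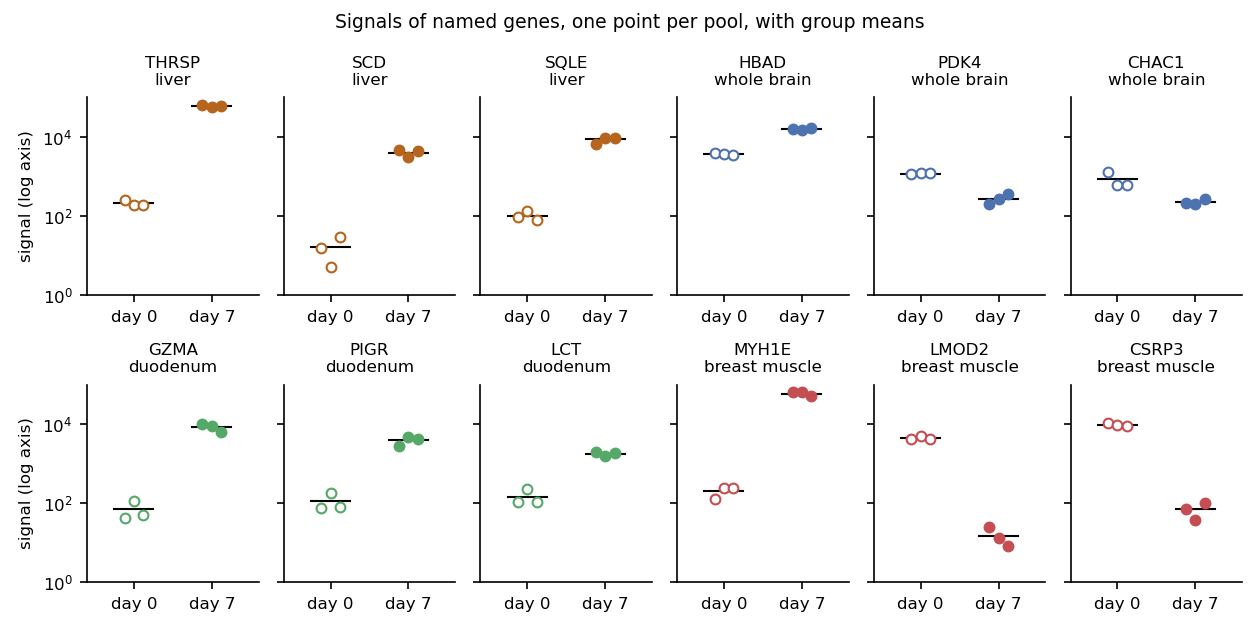
Signals of 12 named genes in the 3 pools of day 0 (open) and of day 7 (filled) of the tissue given above each panel, on a log axis, with bars at the group means. The pools of the ages do not overlap in any panel, and liver THRSP moves from a mean of 212 to 60300.

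In whole brain, few transcripts changed, and those of red blood cells were among them. HBAD and HBA1, alpha globins of red blood cells, rose from 3730 ± 195 to 15800 ± 1030 (log2 change 2.07 ± 0.19, adjusted p = 7.18e-07) and from 13100 ± 1370 to 36700 ± 1510 (1.49 ± 0.14), and the globin HBBR rose by 2.11 ± 0.34 (1.19 to 2.87 with other added values). Of 15 red blood cell genes 3 rose and 0 fell (median 0.64, adjusted p = 5.86e-10), and 5 rose adjusted over the list alone. Antigen presentation genes were higher as a list (median 0.41, adjusted p = 3.26e-05). CD74 rose by 1.39 ± 0.16 and BLB1 by 1.13 ± 0.18, for BLB1 with 1 of its 4 other probe sets also called. The BLB1 call was lost with brain fitted alone (adjusted p = 0.177), and 6 of 11 members rose adjusted over the list alone. Cholesterol synthesis was also higher as a list (median 0.27, adjusted p = 9.63e-05, and 0.0248 with an estimated correlation). INSIG1, a sterol-regulated inhibitor of the pathway, was its 1 called member of 17, at 0.72 ± 0.15, and its 2 other probe sets were not called.

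Among genes without overlap between the ages, the largest falls in brain were of PDK4, from 1190 ± 43.9 to 277 ± 75.4 (log2 change -2.02 ± 0.22, adjusted p = 1.18e-05), the secreted glycoprotein STC2 (-1.77 ± 0.31), CHAC1 (-1.69 ± 0.29, lost under 4 of 19 alternatives), C1orf210 (-1.36 ± 0.27, from -2.23 to -0.60 with other added values and lost under 9 of 19 alternatives) and KLF9, a transcription factor induced by glucocorticoid and thyroid hormone (-1.05 ± 0.15). KLF9 was the 1 called member of 22 of the growth hormone, IGF and thyroid list, which was lower as a whole (median -0.20, adjusted p = 0.00292, 2 lower adjusted over the list alone), though not without day 0 pool 1 (adjusted p = 0.0567). The carbonic anhydrase CA15L and the protease inhibitor A2M rose by 1.43 ± 0.26 and 1.39 ± 0.25, and the other probe set of A2M was not called. Of 16 astrocyte genes 1 was called, AGT, at 0.99 ± 0.21 (list adjusted p = 0.529, also 1 adjusted over the list alone, with a median of -0.07 but a test direction upward), and its other probe set was not. Of 23 myelin, 36 synapse, 27 neural progenitor and 59 cell cycle genes, 0 were called, in each list also when adjusted over the list alone. Their median changes were 0.12, 0.05, -0.14 and 0.19. Myelin (adjusted p = 0.516) and synapse (0.985) did not pass, and the calls of the progenitor list (adjusted p = 0.033) and the cell cycle list (5.83e-05) were lost, with adjusted p = 0.139 and 0.204 with an estimated correlation.

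The whole brain total of 60 probe sets, 34 higher and 26 lower, stands beside 1610 at an unadjusted p under 0.05, and 10 of 38 lists passed camera, 4 of them also with an estimated correlation. Another lost call was of interferon response (1 of 22 rose, adjusted p = 0.0166, and 0.284 with an estimated correlation). The others were of 3 lists without a called member, oxidative phosphorylation (test direction down, 1.07e-09, and 0.161 with an estimated correlation), ribosomal proteins (down, 4.12e-05, and 0.446 with an estimated correlation) and slow sarcomere (down, 0.00764, and 0.133 with an estimated correlation). The count ranged from 13, with brain fitted alone, to 362, with array weights, and was 18 without the arrays of low 5′ signal, where the calls of HBBR, CA15L, A2M, STC2, CHAC1, C1orf210, AGT, INSIG1, FKBP5, LOXL1 and PMP22 were lost. Without day 0 pool 1 it was 32, without day 0 pool 3 35, without day 7 pool 1 37, without day 7 pool 2 39 and without day 7 pool 3 26.

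In duodenum, the transcripts of T cells, antigen presentation and interferon response rose together with those of digestion and absorption. GZMA, a protease of cytotoxic lymphocytes, rose from 69.8 ± 41.7 to 8480 ± 1780, a log2 change of 6.49 ± 0.36 (adjusted p = 5.69e-12), GNLY by 4.28 ± 0.21 and the chemokine XCL1 by 3.64 ± 0.42. Of 13 T cell and cytotoxic cell genes 8 rose and 0 fell (median 1.43, adjusted p = 1.33e-08, 9 adjusted over the list alone). Of 11 antigen presentation genes 10 rose and 0 fell (median 2.08, adjusted p = 1.71e-13, 10 adjusted over the list alone), with BF2 at 3.86 ± 0.23, BLB1 at 2.57 ± 0.18 and beta-2 microglobulin (B2M) at 2.52 ± 0.32. Of 22 interferon response genes 21 rose, and 22 adjusted over the list alone (median 2.17, adjusted p = 6.74e-20). The antiviral genes MX1, IFIT5 and OASL rose by 4.84 ± 0.51, 4.06 ± 0.48 and 3.92 ± 0.45. PIGR, which carries antibodies across the epithelium, rose from 113 ± 60.1 to 3970 ± 1040 (4.87 ± 0.37), and the immunoglobulin genes IGLL1 and JCHAIN rose from 54.1 ± 37 to 1230 ± 1120 and from 35.3 ± 39.4 to 891 ± 678. Of 12 B cell and plasma cell genes 5 rose (7 adjusted over the list alone), with an adjusted p of 0.0054, and 0.128 with an estimated correlation.

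Brush border genes of digestion and nutrient transport rose in 14 of 26 cases and fell in 2 (median 0.94, adjusted p = 2.69e-09, 17 and 2 adjusted over the list alone). LCT, a disaccharidase, rose from 147 ± 71.9 to 1800 ± 242 (log2 change 3.44 ± 0.44), the fructose transporter SLC2A5 by 3.34 ± 0.28 and the calcium-binding protein CALB1 by 2.65 ± 0.43. Of 20 lipid absorption genes 12 rose and 1 fell (median 0.93, adjusted p = 1.6e-07, 12 and 1 adjusted over the list alone), with the lipid receptor SCARB1 at 3.07 ± 0.25, the apolipoprotein APOA4 at 2.85 ± 0.34 and the carotenoid cleavage enzyme BCO1 at 1.73 ± 0.29. Cholesterol synthesis rose in 14 of 17 genes and fell in 1 (median 1.90, adjusted p = 2.48e-18, 14 and 1 adjusted over the list alone), with INSIG1 at 3.63 ± 0.15, SQLE at 3.36 ± 0.20 and HMGCS1 at 3.15 ± 0.19. Of 22 xenobiotic and bile acid genes 9 rose and 3 fell (median 0.39, adjusted p = 0.000975, 9 and 3 adjusted over the list alone). The cytochromes CYP1A1, CYP2D6 and CYP1A2, which oxidise foreign compounds, rose by 4.86 ± 0.35, 3.19 ± 0.16 and 2.87 ± 0.30. Other large rises without overlap between the ages were those of the carbonic anhydrase CA7 (5.40 ± 0.43) and of the metalloreductase STEAP4 (4.94 ± 0.37).

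Genes of cell division and of connective tissue fell in duodenum. Of 59 cell cycle genes 52 fell and 0 rose (median -1.27, adjusted p = 1.03e-19), and 55 fell adjusted over the list alone. MCM5, CDC20 and RRM2 changed by -1.82 ± 0.36, -1.71 ± 0.21 and -1.71 ± 0.22. Of 35 extracellular matrix genes 23 fell and 1 rose (median -0.78, adjusted p = 1.56e-07, 24 and 1 adjusted over the list alone), with the collagens COL14A1 at -3.29 ± 0.23 and COL6A3 at -1.60 ± 0.16 and the proteoglycan FMOD at -1.52 ± 0.23. Young neuron and neural progenitor genes were lower as well, 12 of 27 with 0 higher (median -0.71, adjusted p = 0.00168, and 0.032 with an estimated correlation). Adjusted over the list alone, 15 were lower. SOX11 changed by -1.97 ± 0.48, ELAVL4 by -1.68 ± 0.33 and STMN2 by -1.55 ± 0.28. The largest falls without overlap between the ages were those of the proton pump ATP12A, from 2000 ± 392 to 96.6 ± 79.4 (-4.19 ± 0.40), of PLEKHH1 (-3.40 ± 0.39, and -4.20 to -2.28 with other added values), of the pancreatic protein PDIA2 (-3.32 ± 0.58), of C6orf58 (-3.29 ± 0.57) and of COL14A1. Secretory and enteroendocrine genes moved both ways, with 3 of 16 higher and 2 lower (median -0.12 but a test direction upward, adjusted p = 0.845, 4 and 3 adjusted over the list alone). The protease inhibitor SPINK5 changed by -2.29 ± 0.22, the mucus protein FCGBP by 1.66 ± 0.41, with 4 of its 5 other probe sets called, and REG4 by 1.46 ± 0.34.

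Markers of pancreas, which lies against the duodenum, also changed in both directions, with 4 of 18 higher and 7 lower (median -0.74, adjusted p = 0.542, 4 and 8 adjusted over the list alone). The hormone PPY changed by -3.10 ± 0.43 (-4.03 to -1.93 with other added values), the colipase CLPS by -2.62 ± 0.34 and the protease CTRC by -2.55 ± 0.64, from 28300 ± 13700 to 4490 ± 465. In total 2317 probe sets rose and 3631 fell in duodenum, and the share of higher calls, 39%, became 47.8% with median centring and 49.4% with duodenum fitted alone. Of 38 lists 16 passed camera, 10 of them also with an estimated correlation. The call of B cells was lost. So were those of fatty acid oxidation (6 of 22 rose, adjusted p = 0.00306, and 0.118 with an estimated correlation), myeloid cells (0.000145, and 0.139 with an estimated correlation), ribosomal proteins (29 of 60 fell, 2.48e-06, and 0.403 with an estimated correlation), circadian clock (0.00818, and 0.0623 with an estimated correlation) and adipocytes (4 of 12 rose and 2 fell, 0.0383, and 0.161 with an estimated correlation). Without the arrays of high control signal 5254 probe sets were called, 2026 higher and 3228 lower, and CTRC was not (adjusted p = 0.055), while duodenum fitted alone gave 3011.

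In breast muscle, sarcomere genes changed in both directions. MYH1E, a fast myosin heavy chain, rose from 207 ± 69.3 to 59500 ± 7600, a log2 change of 8.02 ± 0.38 (adjusted p = 1.61e-13), while the heavy chain MYH1B fell from 34700 ± 3000 to 2210 ± 457 (-3.98 ± 0.40). These heavy chain genes are close copies of each other, and cross-hybridisation between them was not tested. AMPD1, a nucleotide enzyme of fast fibres, rose by 3.26 ± 0.58. Of 28 fast sarcomere and calcium handling genes 11 rose and 3 fell (14 and 3 adjusted over the list alone), with an adjusted p of 0.0054, and 0.155 with an estimated correlation. With quantile normalization this list did not pass either (median 0.29, adjusted p = 0.153). Of 17 slow, cardiac and embryonic sarcomere genes 10 fell and 4 rose (11 and 4 adjusted over the list alone), with an adjusted p of 0.00974, and 0.14 with an estimated correlation. CSRP3, a Z-disc protein of slow and cardiac muscle, fell from 9750 ± 1140 to 71.4 ± 33.3 (-6.66 ± 0.33), the slow myosin-binding protein MYBPC1 changed by -3.72 ± 0.45 and the slow light chain MYL3 by -3.55 ± 0.33.

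Other large rises in muscle without overlap between the ages were of RPL3L, a muscle form of a ribosomal protein (5.82 ± 0.33), CCDC180 (5.45 ± 0.28), INSIG1 (5.25 ± 0.15, from 679 ± 129 to 26500 ± 372) and the phosphatase DUSP29 (4.87 ± 0.28). The other large falls were of LMOD2, an actin filament protein of cardiac muscle, from 4460 ± 434 to 15.3 ± 8.56 (-6.70 ± 0.26, and -7.73 to -5.25 with other added values), of ADPRHL1 (-5.70 ± 0.34), of CGTL (-5.23 ± 0.31) and of the M-band protein MYOM3 (-4.74 ± 0.35). MSTN, which encodes the growth inhibitor myostatin, rose from 368 ± 106 to 4120 ± 286 (3.42 ± 0.33), while MYF5 of muscle precursors and the adhesion molecule NCAM1 changed by -1.52 ± 0.44 and -1.68 ± 0.26. For NCAM1, 1 of 2 other probe sets was also called. Of 22 myogenic and satellite cell genes 2 rose and 6 fell, also when adjusted over the list alone (adjusted p = 0.569, and 0.0472 with fry).

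Cell cycle genes rose in muscle, 40 of 59 against 3 that fell (median 1.00, adjusted p = 9.32e-13, and 0.0275 with an estimated correlation). Adjusted over the list alone, 45 rose and 3 fell. AURKB rose by 2.07 ± 0.33, CDC45 by 2.07 ± 0.19 and NCAPG by 1.86 ± 0.26. Cholesterol synthesis rose in 15 of 17 genes and fell in 1 (median 1.89, adjusted p = 1.06e-14, 15 and 1 adjusted over the list alone), with SQLE at 3.63 ± 0.20 and FDPS at 3.16 ± 0.22. Extracellular matrix genes fell in 18 of 35 cases, also adjusted over the list alone, and 0 rose (median -0.55, adjusted p = 3.07e-07). The collagens COL12A1 and COL11A1 changed by -3.19 ± 0.16 and -2.89 ± 0.30, the latter with 2 of 3 other probe sets called, and FMOD by -2.73 ± 0.23.

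Lists of energy metabolism passed camera in muscle with the preset correlation alone. Of 14 glycolysis genes 8 rose and 2 fell, also adjusted over the list alone, with HK1, PGAM1 and GPI at 2.12 ± 0.18, 1.38 ± 0.13 and 1.32 ± 0.12 (adjusted p = 0.00698, and 0.161 with an estimated correlation). Of 62 oxidative phosphorylation genes 29 rose and 7 fell (32 and 7 adjusted over the list alone), with NDUFS6 at 1.53 ± 0.31, UQCR10 at 1.41 ± 0.46 and COX5A at -1.61 ± 0.17 (adjusted p = 0.000266, and 0.416 with an estimated correlation). With quantile normalization neither list passed, glycolysis with a median of 0.57 (adjusted p = 0.074) and oxidative phosphorylation with 0.17 (0.281). Of 22 fatty acid oxidation genes 13 fell and 3 rose, or 14 and 3 adjusted over the list alone (adjusted p = 0.00149, and 0.0912 with an estimated correlation), and PDK4 fell from 29800 ± 3850 to 1400 ± 517. Of 21 genes of starvation-responsive proteolysis 7 fell and 2 rose, also adjusted over the list alone (adjusted p = 0.0833). The list passed with quantile normalization (median -0.46, adjusted p = 0.0268) and, set against no change and not against the other genes, with fry (0.000119). Among them were the ubiquitin ligase FBXO32 at -1.77 ± 0.28, the mitophagy gene BNIP3 at -1.37 ± 0.12 and the stress gene DDIT4 at 1.52 ± 0.53.

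The muscle total was 3054 probe sets higher and 4004 lower. Centring each array on its median turned the share of higher calls from 43.3% to 55.9%, as it moved the median change over probe sets from -0.021 to 0.096. Of 38 lists 11 passed and 3 held with an estimated correlation. The other lost calls were antigen presentation (6 of 11 rose and 1 fell, adjusted p = 0.00974, and 0.147 with an estimated correlation), ribosomal proteins (10 of 60 rose and 2 fell, 0.005, and 0.616 with an estimated correlation) and adipocytes (5 of 12 fell, 0.0101, and 0.104 with an estimated correlation). With quantile normalization the ribosomal list had a median of -0.13 (adjusted p = 0.0886), and the calls of UQCR10 and DDIT4 were lost when single arrays were left out.

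**Figure D4:**
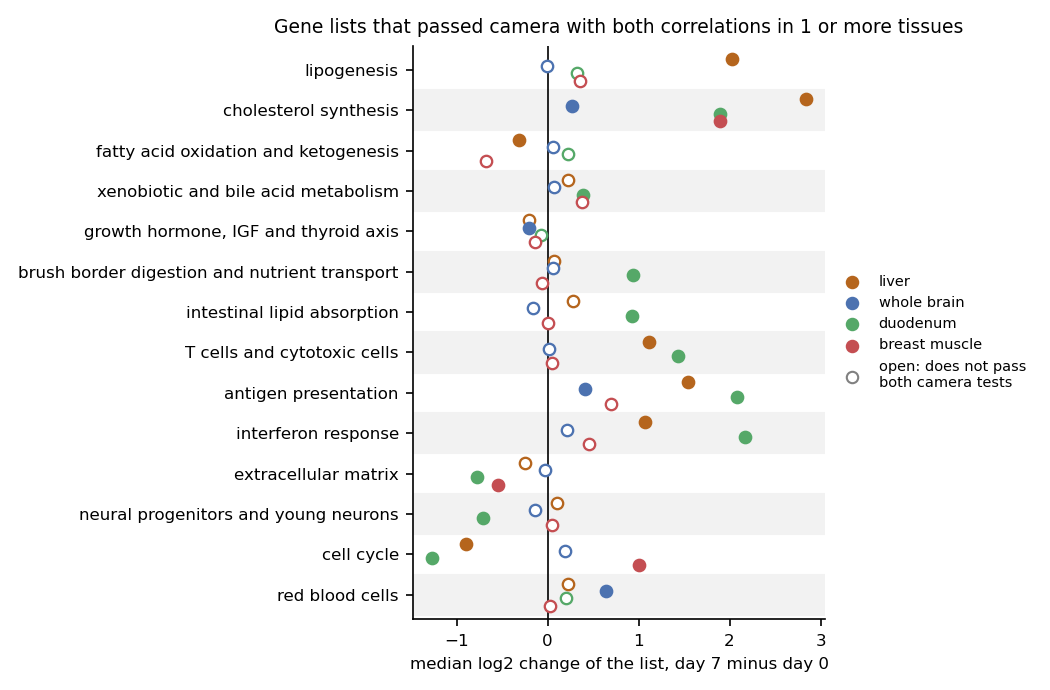
Median log2 change from day 0 to day 7 of 14 gene lists in each tissue (filled where camera passed with both the preset and the estimated correlation, open otherwise). Cholesterol synthesis lies above 0 in the 4 tissues, and cell cycle genes lie at -0.90 in liver, 0.19 in brain, -1.27 in duodenum and 1.00 in muscle.

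The age effect differed between tissues for 7821 probe sets (30.4%). Cell cycle genes had opposite directions, with a median difference of -2.26 between duodenum and muscle (adjusted p = 1.11e-25, and 0.00225 with an estimated correlation) and of -1.84 between liver and muscle (adjusted p = 1.11e-25, and 0.00225 with an estimated correlation). Lipogenesis rose more in liver than in brain, duodenum or muscle, by medians of 2.03, 2.39 and 2.41, and interferon response rose more in duodenum than in liver by a median of 0.99 (liver minus duodenum -0.99, adjusted p = 9.21e-08, and 0.0196 with an estimated correlation). Of 228 tests of list differences, 88 passed and 40 also did so with an estimated correlation.

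Single genes turned in opposite directions. CYP1A1 was lower at day 7 in liver and higher in duodenum, a difference of -7.12 ± 0.50 (adjusted p = 9.19e-10). CGTL and CDO1, an enzyme of cysteine breakdown, rose in liver, by 1.70 ± 0.31 and 5.04 ± 0.24, and changed by -5.23 ± 0.31 and -1.86 ± 0.24 in muscle. CYP2D6 and MST1 rose in duodenum, by 3.19 ± 0.16 and 3.57 ± 0.31, and changed by -3.06 ± 0.16 and -2.38 ± 0.31 in muscle. With other added values the fall of MST1 ranged from -3.01 to -1.45. CCDC180 rose by 5.45 ± 0.28 in muscle and changed by -1.02 ± 0.28 in duodenum (-1.62 to -0.47 with other added values). There its signals were 69.3 ± 32.2 and 20.4 ± 18.5, and its other probe set was not called. Its call was lost under 6 of 19 alternatives, among them leaving out the arrays of high control signal (adjusted p = 0.217).

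Few genes were called in the same direction in the 4 tissues, a count limited by the 60 probe sets called in brain. Of all probe sets, 9 rose and 9 fell in each tissue, where independent lists of these sizes give 0.0193 and 0.035, a figure that does not allow for chicks shared between tissues. The named genes among the rising ones were HBAD, INSIG1 and the class II chaperone CD74. INSIG1 rose by 2.63 ± 0.15 in liver, 0.72 ± 0.15 in brain, 3.63 ± 0.15 in duodenum and 5.25 ± 0.15 in muscle, and HBAD by 1.49 ± 0.19, 2.07 ± 0.19, 1.30 ± 0.19 and 1.17 ± 0.19. CD74 rose by 2.70 ± 0.16, 1.39 ± 0.16, 2.49 ± 0.16 and 0.70 ± 0.16. The falling ones were FKBP5, a glucocorticoid-induced chaperone (-2.51 ± 0.17, -0.98 ± 0.17, -1.65 ± 0.17 and -3.68 ± 0.17 in the same order), STC2 (-0.96 ± 0.31, -1.77 ± 0.31, -0.88 ± 0.31 and -3.71 ± 0.31), the collagen crosslinking enzyme LOXL1 (-1.58 ± 0.19, -0.97 ± 0.19, -1.89 ± 0.19 and -0.59 ± 0.19) and the membrane protein PMP22 (-0.47 ± 0.15, -0.88 ± 0.15, -0.95 ± 0.15 and -0.71 ± 0.15). Across liver, duodenum and muscle 136 probe sets rose and 234 fell together, where independence gives 14.7 and 34.7. For FKBP5 in brain 1 of 2 other probe sets was called, and for INSIG1 in brain 0 of 2. The calls of HBAD and CD74 held under each alternative, and those of INSIG1 (11 of 19) and FKBP5 (4 of 19) in brain were lost under some. So were those of STC2 in liver (10 of 18), brain (5 of 19) and duodenum (11 of 19), LOXL1 in brain (8 of 19) and muscle (3 of 18) and PMP22 in liver (10 of 18) and brain (5 of 19). The total of 18 was 11 without breast muscle day 7 pool 2, 10 without the brain arrays of low 5′ signal and 28 without the duodenum arrays of high control signal.

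**Figure D5:**
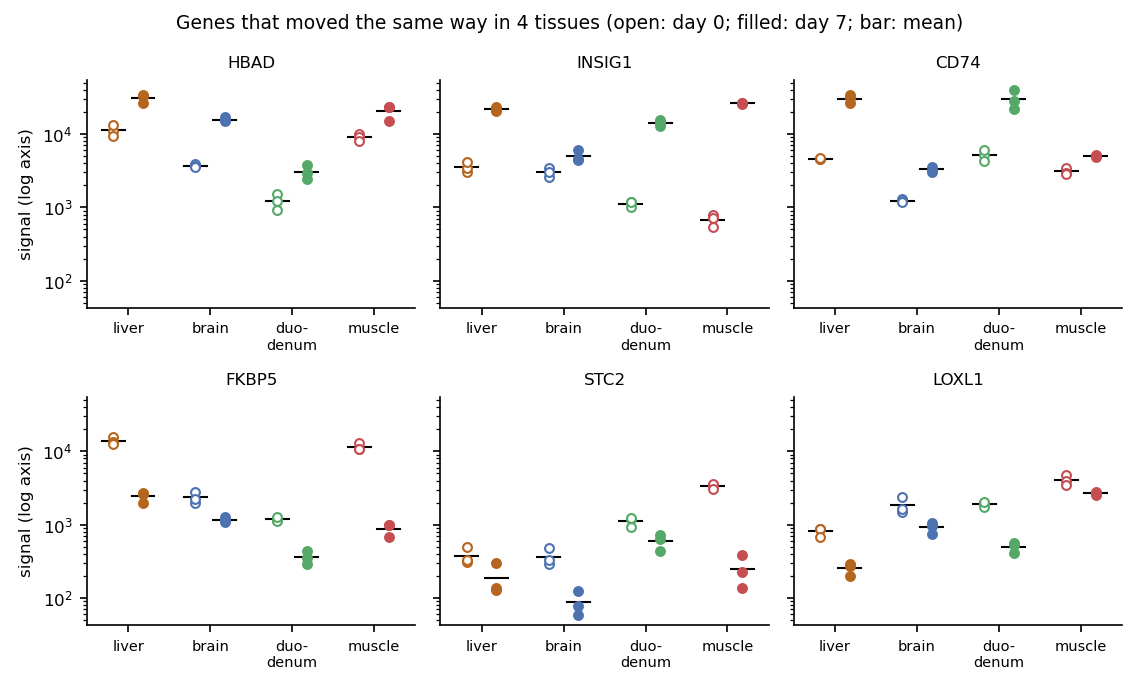
Signals of 6 genes that were called in the same direction in the 4 tissues, on a log axis, for the 3 pools of day 0 (open) and of day 7 (filled) of each tissue, with bars at the group means. HBAD, INSIG1 and CD74 lie higher at day 7, and FKBP5, STC2 and LOXL1 lower.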

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

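Tests chosen only after the result was seen were those of HINTW against other W-linked probe sets and between same-numbered pools, the control signals of the 2 duodenum arrays and the ATF4-dependent list in breast muscle.

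The age effect differed between tissues by a test of the difference itself for 7821 probe sets. Of 80 splits drawn 1 reached this, the real split (highest other 2962). The pairs of tissues differed at 1139 probe sets for liver and brain (highest other split 213), 2175 for liver and duodenum (1133), 5222 for liver and muscle (2433), 2687 for brain and duodenum (1050), 3769 for brain and muscle (3110) and 6251 for duodenum and muscle (3155). In each pair 1 split of 80 reached the real count. These splits shuffled the ages within every tissue, which removes the age effects themselves and not only their differences. They set the counts against no age effect in any tissue, without allowing for chicks shared between tissues. By themselves they cannot show that the effects differ. For the 18 probe sets shared by the 4 tissues 1 split of 80 did so (highest other 0), and 1 of 80 for the enriched ones in liver (480 against 0), brain (1643 against 31), duodenum (520 against 0) and muscle (599 against 7). As other splits within liver or muscle call at most 2 probe sets, and splits that mix tissues leave few 4-fold above each of the others, these counts could hardly rise, and the splits show little here.

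For the age effect within a tissue the 10 splits are too few for a share under 0.05. The real counts and the highest of the other splits were 2958 and 2 in liver, 60 and 117 in brain, 5948 and 1008 in duodenum and 7058 and 2 in muscle, and the number of splits as large, the real one included, was 1, 2, 1 and 1. The brain split with 117 set day 0 pool 1 and day 7 pools 1 and 3 against the rest, which placed the 2 arrays of low 5′ signal together, but 3 other splits that also did so gave 0, 0 and 1 calls. The duodenum splits with 196, 428, 737 and 1008 calls were those that placed the 2 arrays of high control signal together, and the others gave 0. For gene lists the real counts and the highest others were 11 and 13 in liver, 10 and 5 in brain, 16 and 16 in duodenum and 11 and 9 in muscle, with 2, 1, 2 and 1 splits as large. With an estimated correlation they were 7, 4, 10 and 3 lists, against 1, 1, 0 and 1.

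The tested differences of single genes in opposite directions were those of CYP1A1 for liver minus duodenum (-7.12), CGTL (6.93) and CDO1 (6.91) for liver minus muscle, and CCDC180 (-6.46), CYP2D6 (6.25) and MST1 (5.95) for duodenum minus muscle. The cell cycle list differed by a median of -1.13 for liver minus brain, -1.84 for liver minus muscle, 1.46 for brain minus duodenum and -2.26 for duodenum minus muscle. The fatty acid oxidation list differed by -0.59 for liver minus duodenum and 0.93 for duodenum minus muscle, and the adipocyte list by 0.76 for duodenum minus muscle.

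HINTW, which males lack, had signals of 1797 to 15930 in 24 pools labelled male. Its probe set was kept and tested for age with the others. Whether uneven sex between pools entered the age comparison was not tested. As deviations from group means, HINTW correlated with the mean of 19 other W-linked probe sets at r = 0.97 (adjusted permutation p = 2e-05, n = 24). This argues against a probe set that reads its Z-linked copy alone. Pools with more HINTW had less Z-linked relative to autosomal signal (r = -0.69, p = 0.0068, and -0.55 without the 2 farthest arrays), as a hypothesis of pools that differ in their share of females needs. Same-numbered pools of one age had similar HINTW signals across tissues (mean r = 0.93, exact one-sided p = 0.00064), as a hypothesis of same-numbered pools that share chicks needs. If they do, the arrays are not independent, as the permutations above took them to be, and the permutation p-values would be too small. The W-linked and Z-linked signals together argue against males alone in the pools as a set, though not for each pool singly. The sex of single chicks was not measured here.

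The control signal was 11500 on duodenum day 0 pool 2 and 19990 on day 7 pool 1, above the highest of the other 22 arrays by 1.87-fold and 3.26-fold. Less labelled target on these arrays would give this, but so would more control transcript, and the amounts added are not known here. The median signals of these arrays were 132.1 and 146, against 85.13 to 100.1 on the other duodenum arrays. This argues against more control transcript alone, which would leave the other probe sets as they were. The amount of labelled target itself was not measured here. Without these arrays the log2 changes of 5931 called probe sets had a median ratio of 0.977 to those with them, 5931 in the same direction. Of these, 4517 stayed called, which argues against the 2 arrays as the source of most duodenum age calls. The probe sets were chosen with the arrays included, and both fits share the other arrays, which favours the same direction. No biological explanation was tested.

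FKBP5 and STC2 fell in the 4 tissues, with calls lost under some alternatives for FKBP5 in brain (4 of 19) and for STC2 in liver (10 of 18), brain (5 of 19) and duodenum (11 of 19). CHAC1 fell in liver, brain and duodenum but not in muscle, where it rose by 1.14 ± 0.29 (lost under 4 of 19 alternatives in brain and 1 of 18 in muscle), and PDK4 in liver, brain and muscle but not in duodenum (0.09 ± 0.22, adjusted p = 0.826). Lists that may share a cause with these genes were tested without them with camera in limma, with unadjusted p given for the preset and then the estimated correlation. The test that glucocorticoid-responsive genes fall together needed 3 tissues and found a fall in 2 with the preset correlation, muscle (0.00163 and 0.0174) and brain (0.014 and 0.0552, 0 of 14 called), of which muscle alone held with both, and the direction in duodenum was upward (0.0198 and 0.0675). For ATF4-dependent genes it found 1, duodenum (0.0302 and 0.0685), which did not hold with both, while in muscle the list rose by a median of 0.49 (0.00303 and 0.0167), which argues against it as the source of the fall of STC2 there. For heat shock chaperones it found 2, liver (0.000839 and 0.0281) and duodenum (0.0158 and 0.1), of which liver alone held with both. Their direction in brain was upward (0.019 and 0.109, 0 of 21 called). In muscle the chaperones had a median of 0.07 (0.673 and 0.764), so of these lists the glucocorticoid one alone fell there. In liver neither the glucocorticoid list (median -0.06, 0.835 and 0.863) nor the ATF4-dependent list (0.09, 0.93 and 0.938) fell. No list fell in every tissue where these genes did. Outside the ATF4-dependent list in muscle these explanations cannot be told apart, and age itself stays open, as untested.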

How the results depend on the processing

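Alternatives chosen only after the data were examined were leaving out the arrays that stood apart, the ratio of 5′ to 3′ signal as a covariate, and every alternative for the pairs of tissues and for list differences. The whole brain count of 60 moved to 96 with quantile normalization, 36 with median centring, 36 with no intensity trend, 362 with array weights, 13 with each tissue fitted alone, 39 at 2-fold or more and 18 without the arrays of low 5′ signal. The 18 shared probe sets became 11 with median centring, 9 with no intensity trend, 44 with array weights, 28 without the arrays of high control signal and 10 without those of low 5′ signal. Array weights also gave 4924 in liver and, for the pairs, 2422 (liver and brain), 4042 (liver and duodenum), 4948 (brain and duodenum) and 6263 (brain and muscle). Duodenum fitted alone gave 3011. At 2-fold or more, 1370, 2767 and 3597 stayed in liver, duodenum and muscle. The liver and brain pair became 1915 without the arrays of high control signal and 728 without those of low 5′ signal. Lists passing were 7, 4, 10 and 3 with an estimated correlation and 20, 5, 25 and 23 with fry, in the order liver, brain, duodenum and muscle, and 40 of 88 list differences held with an estimated correlation. With quantile normalization 52 of 59 lists were the same. The ribosomal list in muscle turned to -0.13, and the calls of adipocytes in duodenum (0.0501) and of fast sarcomere, glycolysis and oxidative phosphorylation in muscle were lost. The cause was not tested for any of these. Leaving out 1 array at a time gave 26 to 48 in brain, 11 to 20 for the shared probe sets, 2037 to 2390 in liver, 4747 to 5785 in duodenum, 5577 to 6043 in muscle and 6727 to 8539 for differences between tissues.

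With the replicate number as a block, within tissue for age effects and within age for differences between tissues, the counts were 2275 in liver, 19 in brain, 4980 in duodenum, 6131 in muscle, 10 shared and 7861 for differences between tissues. Within a tissue 12 of 24 arrays correlated best with their own number, and same-numbered arrays correlated at -0.44 to 0.38, with 2 of 12 pairs above 0.1, so the number does not pair the ages of a tissue. Between tissues 16 of 24 arrays did so, a hint from the data, not the design, and the block within age allows for it.

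No called gene among those named reversed under any alternative, while PDK4 in duodenum, not called, ranged from -0.09 to 0.34. Of 207 compared, 206 kept their call with array weights, 194 with the block, 198 with the 10th percentile added, 200 without a filter, 200 with median centring, 201 with no intensity trend and 202 with quantile normalization. Fewer could be compared with each tissue fitted alone (173 of 187 kept), without the arrays of high control signal (66 of 69) and without those of low 5′ signal (11 of 22). Of 59 lists 35 were the same with an estimated correlation and 49 with fry. With single arrays left out 1523 of 1602 gene calls and 343 of 354 list calls were the same. Those lost most often were AGT in brain (13 of 19 alternatives), INSIG1 in brain (11 of 19), STC2 in duodenum (11 of 19) and HGD in liver (11 of 18). Lost under 1 or 2 were BLB1, HBBR and KLF9 in brain, LDHA in liver, CTRC, FCGBP and PER2 in duodenum and CHAC1 and MYF5 in muscle. Probe sets near the background may limit what could be called, though their spread was not compared with that of brighter ones here.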

Other observations

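Tests of the groups below were written before the values were seen, but the genes named from them were chosen after.

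Genes of the growth hormone, IGF and thyroid axis moved in both directions. In liver 5 of 22 rose and 6 fell, also adjusted over the list alone (adjusted p = 0.392). IGF1, the main circulating growth factor made by liver, rose there from 3.29 ± 0.493 to 462 ± 138 (log2 change 3.92 ± 0.32). As its day 0 signal lies below the value added before taking logs, this change ranged from 2.36 to 5.51 with other added values. Its binding protein IGFBP1 fell from 14700 ± 2410 to 1950 ± 256 (-2.89 ± 0.27). In breast muscle 3 of 22 rose and 7 fell, or 4 and 7 adjusted over the list alone (adjusted p = 0.358). IGF1 rose there from 14 ± 5.37 to 332 ± 99.5 (3.05 ± 0.32, and 1.85 to 4.02 with other added values), IGFBP2 changed by -2.54 ± 0.31 and the insulin receptor substrate IRS2 by -3.16 ± 0.26, whose other probe set was not called. In duodenum 1 of 22 rose and 4 fell, also adjusted over the list alone (adjusted p = 0.988), with the growth hormone receptor GHR at -1.90 ± 0.22, IGFBP2 at -1.64 ± 0.31 and SOCS3 at 1.58 ± 0.33.

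Genes of myeloid cells and innate defence also moved in both directions. The defensin AvBD1 fell in liver from 4900 ± 1620 to 520 ± 178 (log2 change -3.16 ± 0.33) and changed by -2.33 ± 0.33 in muscle. The cathelicidin CATH1 changed by -3.05 ± 0.47 in liver, -2.33 ± 0.47 in duodenum and -2.51 ± 0.47 in muscle, and its other probe set was not called in duodenum and muscle. The lysozyme gene LYG2 rose in duodenum by 3.43 ± 0.33, where 13 of 27 of these genes rose and 6 fell (adjusted p = 0.000145, and adjusted p = 0.139 with an estimated correlation). In liver 12 of these 27 rose and 6 fell (median 0.59, mean -0.02, adjusted p = 0.0566). Of 14 circadian clock genes 3 rose and 1 fell in liver (adjusted p = 0.193), with BHLHE41, a repressor of the clock, from 255 ± 36.7 to 7430 ± 755 (4.72 ± 0.34), and 6 fell and 0 rose in muscle (adjusted p = 0.191), with NFIL3 at -1.31 ± 0.20 and PER2 at -1.22 ± 0.36. In duodenum 5 of these 14 rose and 1 fell (median 0.42, adjusted p = 0.00818, and 0.0623 with an estimated correlation), with PER2 at 1.39 ± 0.36. For PER2, 1 of its 4 other probe sets was called in muscle and 1 in duodenum. The PER2 call was lost under 2 of 19 alternatives in duodenum and 3 of 18 in muscle. The hours of tissue collection are not known here.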
